A study of Homo sapiens with 6 samples.

How the data were processed

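Total RNA of Caco-2 cells was measured on 6 Affymetrix arrays, 1 per sample, 2 arrays for each of scramble shRNA, FAM46A-shRNA#2 and FAM46A-shRNA#4. Per the labels' protocols, cells received the lentivirus before confluence and were sampled 17 days later, and biotin-labelled sense-strand DNA was prepared with the WT PLUS reagent kit from 100 ng of RNA. Groups and replicate numbers follow the sample titles. The deposited log2 values had been made by the authors from 1 channel per array, and each probe set's values had been set relative to its median over the 6 arrays, which was read from the values themselves. All 48144 probe sets had a median within 1e-06 of 0, and the values ran from -2.65 to 3.53 with 0 missing. Summarisation, background correction, normalization between arrays, software and the base of the logarithm are not given in the sources used here, and log2 was assumed. Centring leaves differences between groups as they were and removes the level of each gene, so signal over background was not analysed here and dim and bright probe sets were treated alike.

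Probe sets were named through the Entrez ID of the platform table, with symbols and gene order from the RefSeq table. Of the probe sets, 16098 had 1 symbol, 0 had several and 32046 had none, and 0 symbols were updated. These gave 14884 genes, 11915 of them protein-coding, and 779 genes had more than 1 probe set, which were averaged. In 252 of these 779, called or not, the probe sets lay on opposite sides of 0 for the mean of both hairpins against scramble. The level of FAM46A and its paralogs was not analysed here.

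Groups were compared in limma 3.58.1 under R 4.3.3 with 1 linear fit of all 6 arrays and 3 groups, moderated variances (eBayes without a trend, 3 residual and 3.09 prior degrees of freedom) and Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. The comparisons were shRNA#2 against scramble, shRNA#4 against scramble, the mean of both hairpins against scramble, and shRNA#2 against shRNA#4. The median SE of a log2 change was 0.0657, and 0.0569 for the mean of both hairpins. The labels call the arrays biological replicates of 1 cell line, and what separates them is not given in the sources used here, so the p-values measure only the spread between these samples. Overlaps were set beside independent lists and beside 100 simulated draws. In these draws all 6 arrays were simulated without change, and both hairpin groups shared the 2 simulated scramble arrays. With 2 arrays per group, no formal test of outlying arrays or of other splits of the samples was run. A single unusual scramble array was examined for the apolipoprotein and brush border lists only, and each array was left out in turn.

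Before the data were examined, 30 gene lists with 868 members were fixed, of which 29 had measured members, 501 in all, and replication-dependent histones had 0. Lists were tested with camera (limma) at its preset correlation of 0.01, with the correlation estimated from the residuals as an alternative and fry as another tool. Members were counted over all genes and adjusted over the list alone. Named genes followed a rule fixed at the same time. It took the 12 largest rises and falls for the mean of both hairpins whose 4 hairpin arrays lay on one side of both scramble arrays, the 5 largest each way for each hairpin by the same condition and between the hairpins without it, and up to 4 members of a list with the largest changes for the mean of both hairpins. Symbols of non-coding and olfactory receptor families were counted and not named.

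The fixed design was changed in 3 points once the values were seen to be centred. The brightest probe set of a gene could not be chosen, so probe sets were averaged, the variance trend on signal was dropped, and both fixed choices were run as alternatives on the centred values. Filters on dim probe sets and a log transform with an offset were not run. Other alternatives were quantile normalization, centring of each array, array weights, a robust prior, a replicate block, all probe sets, only the arrays compared, the 4 hairpin arrays as 1 group, a 2-fold minimum, an adjusted p under 0.01 and leaving out each array. Restriction to protein-coding genes and tests of symbol families were chosen after seeing the data.

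The tests were tested on simulated data with 14884 genes and 200 changed genes in 20 draws. A change of 0.5 on the log2 scale was recovered for 92.35% (shRNA#2), 94.5% (shRNA#4), 97.25% (mean) and 93.35% (between hairpins) of changed genes, with 5.00%, 5.41%, 6.04% and 5.00% false among the calls. Of 300 random lists of 20 genes simulated independently, camera gave 4% an unadjusted p under 0.05. These lists do not show how camera behaves where the genes of a list vary together. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.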

Results

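RNA of Caco-2, an established human colon carcinoma line that forms an enterocyte-like epithelium in culture, was profiled on 6 single-channel Affymetrix arrays, 17 days after lentiviral delivery of a short hairpin RNA (shRNA). The 3 groups held 2 arrays each. The control group carried a scramble hairpin, and the other groups carried shRNA#2 or shRNA#4, a pair of different hairpins directed against FAM46A (TENT5A), a member of a family of non-canonical poly(A) polymerases. The comparisons address which transcripts differ after FAM46A depletion, and which of the differences the hairpins share. The level of FAM46A and of its paralogs was not analysed here, so the depletion was not measured and the groups follow the labels alone. Each deposited value was relative to the median of its probe set over the 6 arrays, so only differences between groups are given, for 14884 named genes. The values were taken as log2, a base that the sources used here do not state. Errors after ± are standard errors (SE) of the limma fit with n = 2 arrays per group, and the number of arrays limits their precision. Within a group the arrays correlated at r = 0.768 for scramble, 0.524 for shRNA#2 and 0.648 for shRNA#4 across all probe sets, which are not independent replicates. On centred values this r also depends on how far a group lies from the median of the 6 arrays. The standard deviation of the difference between replicates was 0.1305 for scramble, 0.1205 for shRNA#2 and 0.1250 for shRNA#4, so r does not rank their agreement. The correlations between arrays of different groups lay between -0.36 and -0.17, since each probe set was centred.

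GSTA1, a glutathione transferase of the alpha class, fell by 3.70 ± 0.14 on the log2 scale in the mean of both hairpins against scramble. APOA4, an apolipoprotein of chylomicrons, fell by 2.95 ± 0.096 (7.73-fold). TM4SF20 fell by 2.27 ± 0.084 and GATM, which catalyses the first step of creatine synthesis, by 2.26 ± 0.071. Close behind was APOC3, an apolipoprotein that inhibits lipoprotein lipase (-2.25 ± 0.0945). ZG16, a lectin-like secretory granule protein of goblet cells (-2.25 ± 0.10), and the brush border lactase LCT (-2.13 ± 0.082) followed. The rises were led by KITLG, the ligand of the KIT receptor, at 2.49 ± 0.15 (5.60-fold), and by complement component C5 at 2.27 ± 0.12 (4.81-fold).

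The other large falls were in GSTA2 (-2.09 ± 0.10), KLB, a co-receptor of endocrine fibroblast growth factors (-2.08 ± 0.12), the adhesion receptor ADGRG7 (-2.06 ± 0.115), the flavin monooxygenase FMO5 (-2.02 ± 0.11) and SOAT2, which esterifies cholesterol in enterocytes (-2.02 ± 0.14). How far the probe sets of the close paralogs GSTA1 and GSTA2 cross-hybridise was not analysed here. P3H2, a prolyl hydroxylase of collagen, rose by 1.92 ± 0.069, TMEM47 by 1.90 ± 0.10 and HSPA4L, a heat shock chaperone, by 1.76 ± 0.079. SAMD5 rose by 1.72 ± 0.12, CDCA7L, a nuclear protein that interacts with MYC, by 1.59 ± 0.080, and the neuronal adhesion molecule NRCAM by 1.59 ± 0.092. ULBP1, a stress-induced ligand of the NKG2D receptor, rose by 1.52 ± 0.10, the Mediator subunit MED12L by 1.505 ± 0.074, the homeobox gene HOXB9 by 1.48 ± 0.11 and NRP1, a co-receptor of semaphorins and VEGF, by 1.47 ± 0.098. These 24 genes were the 12 largest changes each way whose 4 hairpin arrays all lay on one side of both scramble arrays. Their adjusted p-values (limma, Benjamini-Hochberg) ran from 0.000166 for GSTA1 to 0.000519 for HOXB9. In 1 alternative, a variance prior that follows the mean of the centred values, the adjusted p of KITLG from limma became 0.346. After centring this mean holds no signal level and moves with a gene's own change, so that alternative decides little about KITLG.

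**Figure D1:**
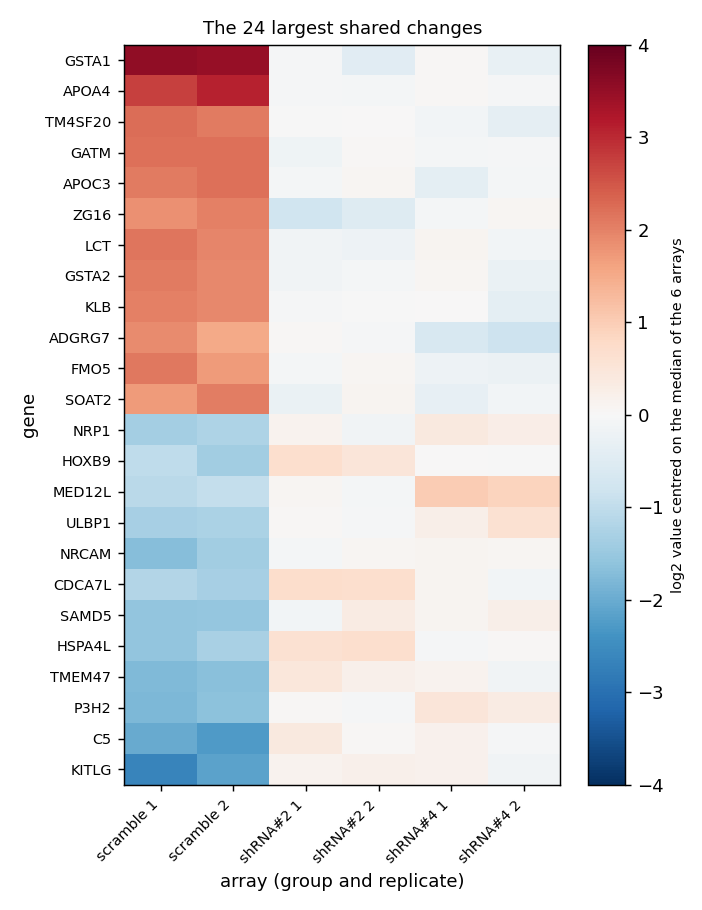
Heat map of the 24 largest changes shared by both hairpins (rows, genes; columns, the 6 arrays by group and replicate), with colour giving the log2 value centred on the median of the 6 arrays, on a scale from -4 to 4. Falls are drawn above rises, and in every row the 4 hairpin arrays lie on one side of both scramble arrays, as for GSTA1 with a change of -3.70 and KITLG with a change of 2.49.

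Over all 14884 genes, 3784 (25.4%) passed the test for the mean of both hairpins against scramble (limma, Benjamini-Hochberg adjusted p under 0.05). Of them 2206 were higher and 1578 lower. Changes of at least 2-fold went the other way in number, with 70 genes higher and 136 lower. The 4 hairpin arrays lay on one side of both scramble arrays for 5390 genes, 36.2% of all. The share would be 13.3% if all arrays were interchangeable. Replicates of a group resemble each other, so any difference between the groups can raise it, and 13.3% is no measure of a shared hairpin effect. Without replicate 1 of scramble 2477 genes passed, and with the 4 hairpin arrays taken as a single group 1756 did.

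Of 22 measured apolipoprotein and plasma protein genes, 19 fell and 0 rose, and adjusted over the list alone 20 fell. The median change of the list was -1.15. Beside APOA4 and APOC3, MTTP, which loads lipid onto apolipoprotein B, fell by 1.59 ± 0.0705, and TTR, a carrier of thyroid hormone and retinol-binding protein, by 1.58 ± 0.16. The set test of limma (camera) gave an adjusted p of 9.75e-16, and adjusted p = 0.0766 with an estimated correlation. Of 30 measured genes of the brush border and absorptive enterocyte, 17 fell and 0 rose, and adjusted over the list alone 20 fell and 1 rose. CDHR5, a protocadherin that links neighbouring microvilli, fell by 1.79 ± 0.048, the disaccharidase SI by 1.49 ± 0.17 and the aminopeptidase ANPEP by 1.23 ± 0.096. The median of this list was -0.29, with a camera (limma) adjusted p of 1.25e-08, and adjusted p = 0.103 with an estimated correlation. The estimated correlations of the apolipoprotein and brush border lists were -0.0044 and 0.004, below the preset 0.01. Correlation between their genes therefore does not explain the weaker results with that alternative. Camera with an estimated correlation relies on 3 residual degrees of freedom, so a list that it does not call is not shown to be unchanged.

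Genes of xenobiotic and bile acid handling were few, with 6 measured of 32. GSTA1, GSTA2, SLC51A and SLC51B fell, 4 of the 6, and 0 rose, while adjusted over the list alone 5 fell and 1 rose. SLC51B, a subunit of the basolateral bile acid exporter, fell by 1.61 ± 0.0985, and the call of its partner SLC51A (-0.54 ± 0.10) ended without replicate 1 of scramble. The list's median was -1.08, with a camera (limma) adjusted p of 0.00107, and adjusted p = 0.296 with an estimated correlation. Of 13 measured genes of fatty acid oxidation and PPAR targets, 7 fell and 2 rose, both over all genes and adjusted over the list alone. CREB3L3, a transcription factor of lipid metabolism, fell by 1.43 ± 0.10, and CPT1A, which admits fatty acids to mitochondria, by 1.13 ± 0.14. Of the fatty acid activating enzymes ACSL5 fell by 1.13 ± 0.084 while ACSL1 rose by 1.15 ± 0.094. The list gave a camera (limma) adjusted p of 0.00912, and adjusted p = 0.296 with an estimated correlation.

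Goblet and mucus genes fell in 7 of 19 measured members and rose in 1, both over all genes and adjusted over the list alone. Beside ZG16, the trefoil peptides TFF2 (-1.32 ± 0.12) and TFF1 (-1.24 ± 0.16) fell. With shRNA#2 alone the list was not called (camera adjusted p 0.0675, limma). The list's median was only -0.10 and its camera (limma) adjusted p 0.00912, with adjusted p = 0.421 with an estimated correlation. Of 22 measured epithelial junction genes, 10 fell and 3 rose, and adjusted over the list alone 11 fell and 5 rose. The tight junction proteins CLDN1 (-1.15 ± 0.043), OCLN (-0.86 ± 0.061), MARVELD3 (-0.85 ± 0.0785) and TJP3 (-0.64 ± 0.064) were among those that fell. This list gave a camera (limma) adjusted p of 0.0155, and adjusted p = 0.327 with an estimated correlation, and was not called with shRNA#4 alone (0.0754).

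Of 23 measured genes of DNA replication and S phase, 17 rose and 0 fell, and adjusted over the list alone 18 rose. The replication factor MCM10 rose by 1.005 ± 0.092, the G1/S cyclin gene CCNE1 by 0.85 ± 0.040, and the helicase subunits MCM2 and MCM3 by 0.74 ± 0.092 and 0.69 ± 0.062. The median of the list was 0.45, with a camera (limma) adjusted p of 9e-08, and adjusted p = 0.413 with an estimated correlation. Of 27 measured mitosis and G2/M genes, 12 rose and 0 fell, and 13 rose adjusted over the list alone. ECT2, a regulator of cytokinesis, rose by 0.49 ± 0.075 and the kinesin KIF23 by 0.47 ± 0.084. The camera (limma) adjusted p was 9.7e-05, and adjusted p = 0.593 with an estimated correlation. With shRNA#4 alone 7 of the 27 rose and the list was not called (camera adjusted p 0.0679, limma), and the scramble arrays themselves differed in it, with medians of -0.277 and -0.027.

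Amino acid and ATF4 target genes rose in 12 of 19 measured members and fell in 0, and adjusted over the list alone 13 rose and 1 fell. ASNS, asparagine synthetase, rose by 1.38 ± 0.12, PSAT1, an enzyme of serine synthesis, by 1.34 ± 0.12, the lipoprotein receptor VLDLR by 1.14 ± 0.078 and the glycyl-tRNA synthetase GARS1 by 1.06 ± 0.053. The list's median was 0.50, with a camera (limma) adjusted p of 3.8e-05, and adjusted p = 0.413 with an estimated correlation. Of 22 measured genes of crypt stem cells and Wnt targets, 10 rose and 0 fell, and adjusted over the list alone 10 rose and 1 fell. LGR5, a receptor that marks crypt base stem cells, rose by 1.41 ± 0.17, the adhesion receptor CD44 by 1.15 ± 0.11, the transcription factor SP5 by 1.12 ± 0.045 and cyclin D1 (CCND1) by 0.998 ± 0.089. The median of this list was 0.17, with a camera (limma) adjusted p of 0.00224, and adjusted p = 0.296 with an estimated correlation.

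The camera test called 3 further lists with more rises than falls. Cytoplasmic ribosomal protein genes rose in 5 of 26 measured members and fell in 0, with the same counts adjusted over the list alone, and RPS23 and RPS6 rose by 0.28 ± 0.042 and 0.27 ± 0.040. The limma camera adjusted p was 0.00565, and adjusted p = 0.413 with an estimated correlation. Cholesterol synthesis genes rose in 8 of 17 measured members and fell in 2, against 12 and 2 adjusted over the list alone. SQLE, squalene epoxidase, rose by 0.69 ± 0.085 and PMVK, phosphomevalonate kinase, fell by 0.44 ± 0.071. The limma camera adjusted p was 0.0132, and adjusted p = 0.533 with an estimated correlation, and the list was not called with shRNA#4 alone (0.0504). Immediate early and MAPK feedback genes rose in 4 of 18 measured members and fell in 1, and adjusted over the list alone 5 rose and 1 fell. The feedback inhibitor SPRY2 rose by 1.002 ± 0.085, and ATF3, a stress-induced transcription factor, by 0.66 ± 0.056. The hairpins were unequal in both genes. SPRY2 rose by 1.52 with shRNA#2 and was lower with shRNA#4 by 1.03. ATF3 rose by 1.18 with shRNA#4 and was lower with shRNA#2 by 1.03. The limma camera adjusted p was 0.0265, and adjusted p = 0.593 with an estimated correlation, and the list was not called with shRNA#2 alone (0.306). This call ended without replicate 2 of any of the 3 groups, with 1 other choice of probe set per gene, and with fry, which also did not call the mitosis list.

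**Figure D2:**
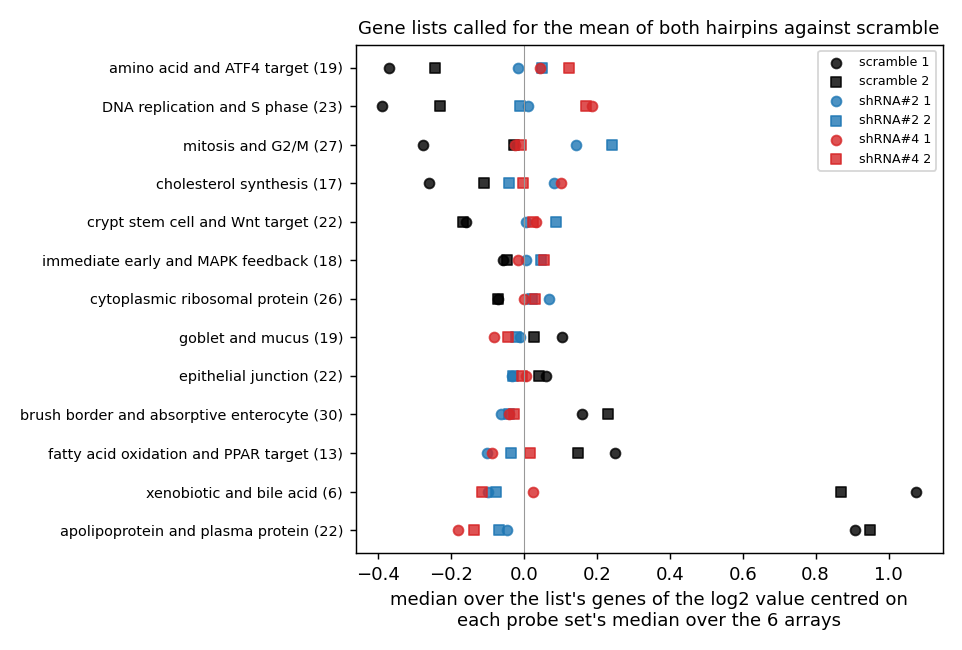
Median over each list's measured genes (vertical axis, with the number measured) of the log2 value centred on the median of the 6 arrays (horizontal axis), with 1 point per array, coloured by group and shaped by replicate, for the 13 lists that camera called for the mean of both hairpins. The scramble arrays lie at 0.91 and 0.95 for the apolipoprotein and plasma protein list and the 4 hairpin arrays between -0.18 and -0.05, while for mitosis and G2/M the shRNA#4 arrays lie close to 1 of the scramble arrays.

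The other 16 lists with measured members did not pass the camera test. Members still changed in several of them, but 25.4% of all genes were called in this comparison. The NRF2, immune and endothelial, Paneth and interferon lists had no larger share of called members than that. Of 18 measured hypoxia and glycolysis genes 5 fell and 2 rose, also adjusted over the list alone, with falls of NDRG1 by 1.35 ± 0.16 and of the mitophagy receptor BNIP3 by 1.06 ± 0.063 and a rise of hexokinase HK1 by 0.75 ± 0.066, and without replicate 1 of scramble this list was called. Of 11 measured YAP targets 4 rose and 1 fell, and adjusted over the list alone 4 rose and 2 fell, with ANKRD1 up by 1.22 ± 0.11. Of 13 NRF2 target and metallothionein genes 2 rose and 1 fell, also adjusted over the list alone, with MT1F down by 1.12 ± 0.22 and TXNRD1, thioredoxin reductase, up by 0.57 ± 0.054. Of 8 immune and endothelial markers 2 fell and 0 rose, and adjusted over the list alone 2 fell and 1 rose. The 2 were CD68 (-2.01 ± 0.17) and LAPTM5 (-0.77 ± 0.13), which both encode lysosomal membrane proteins. Of 10 Paneth and antimicrobial genes 2 fell and 0 rose, also adjusted over the list alone, with lysozyme (LYZ) down by 1.16 ± 0.105.

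Of 30 measured genes of ER translocation and the early secretory pathway 10 rose and 4 fell, also adjusted over the list alone, among them SAR1B, a GTPase needed for chylomicron export, which fell by 0.58 ± 0.046, and SRP72, which rose by 0.38 ± 0.0475. Of 13 unfolded protein response genes 3 rose and 2 fell, also adjusted over the list alone, with CREB3L2 up by 0.45 ± 0.0655 and SEL1L, a part of the degradation machinery of the ER, down by 0.40 ± 0.059. Of 14 genes of the poly(A) tail and mRNA decay machinery 5 rose and 3 fell, and adjusted over the list alone 6 rose and 6 fell. In that list CNOT9, a subunit of the CCR4-NOT deadenylase complex, rose by 0.61 ± 0.063, the poly(A) polymerase TENT4A rose by 0.41 ± 0.0645 and the decapping enzyme DCP2 fell by 0.49 ± 0.063. Of 29 interferon response genes 4 fell and 2 rose, also adjusted over the list alone, with the RNA sensor RIGI down by 0.83 ± 0.081 and EIF2AK2, a kinase activated by double-stranded RNA, up by 0.48 ± 0.060. Of 13 p53 targets 3 rose and 2 fell, also adjusted over the list alone, with TP53INP1 down by 0.90 ± 0.064 and TIGAR up by 0.60 ± 0.081. Of 9 collagen and extracellular matrix genes 2 rose and 1 fell, and adjusted over the list alone 3 rose and 1 fell, with THBS1 up by 1.19 ± 0.13 and the crosslinking enzyme LOX down by 0.77 ± 0.086. Of 11 mesenchymal and fibroblast markers 3 rose and 1 fell, and adjusted over the list alone 3 rose and 2 fell, with TAGLN up by 0.44 ± 0.055. TAGLN stood at 1.11 with shRNA#4 but at -0.23 with shRNA#2, so its mean does not describe a change that the hairpins share.

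In the last 4 lists at most 2 members changed. BMP and TGF-beta targets (16 measured) and NF-kappa-B and inflammatory genes (14 measured) each had 1 rise and 1 fall, also adjusted over the list alone, and the fall in the second was IL18, an epithelial cytokine, by 0.76 ± 0.078. Of 17 measured enteroendocrine markers 1 rose, the peptide hormone gene NTS (0.20 ± 0.045), and of 11 measured genes of oxidative phosphorylation 1 fell, the cytochrome c oxidase subunit gene COX8A (-0.36 ± 0.092). Adjusted over the list alone, neither was called, and both calls over all genes ended without any 1 of the scramble or shRNA#2 arrays. The limma camera adjusted p-values of the 16 lists lay between 0.13 for the Paneth list and 0.972. The median, the mean and the direction of the test differed in sign for YAP targets, p53 targets and several further lists among these 16, and had the same sign in each list called.

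With shRNA#2 alone against scramble, KITLG (2.56 ± 0.18), C5 (2.35 ± 0.14), HSPA4L (2.08 ± 0.091), TMEM47 (2.07 ± 0.12) and RASSF9, a Ras association domain gene (2.01 ± 0.10), rose the most. GSTA1 (-3.76 ± 0.16), APOA4 (-2.98 ± 0.11), ZG16 (-2.58 ± 0.12), GATM (-2.26 ± 0.082) and LCT (-2.21 ± 0.094) fell the most. Their adjusted p-values (limma, Benjamini-Hochberg) lay between 0.000298 and 0.000677. With a variance prior that follows the mean of the centred values, which is not a signal level, KITLG and C5 were not called. Of the 14884 genes 1800 were higher and 1420 lower, 3220 in all, with 75 and 146 of them at least 2-fold. The camera test called 11 lists. In 4 of these the counts for shRNA#2 were 17 falls among apolipoprotein and plasma protein genes (20 adjusted over the list alone), 14 falls and 2 rises in the brush border list (17 and 3 adjusted over the list alone), 16 rises among mitosis genes (19 rises and 1 fall adjusted over the list alone) and 13 rises and 1 fall among S phase genes (14 and 1 adjusted over the list alone). The lowest limma adjusted p over the 11 lists was adjusted p = 0.107 with an estimated correlation, for the apolipoprotein and plasma protein list. The number of called genes, FAM46A-shRNA#2 vs scramble, was 1756 without replicate 1 of shRNA#2, 1892 without its replicate 2 and 2038 without replicate 1 of scramble.

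With shRNA#4 alone, KITLG (2.41 ± 0.18), C5 (2.19 ± 0.14), PTGS2, the inducible cyclooxygenase (2.13 ± 0.11), P3H2 (2.13 ± 0.080) and MED12L (1.98 ± 0.085) rose the most. GSTA1 (-3.63 ± 0.16), APOA4 (-2.92 ± 0.11), ADGRG7 (-2.42 ± 0.13), TM4SF20 (-2.38 ± 0.097) and APOC3 (-2.37 ± 0.11) fell the most. Their adjusted p-values (limma, Benjamini-Hochberg) lay between 0.000229 and 0.000518. With a variance prior that follows the mean of the centred values, which is not a signal level, KITLG and C5 were not called. Of the 14884 genes 2331 were higher and 1553 lower, 3884 in all, with 114 and 165 of them at least 2-fold. The camera test called 12 lists. Among apolipoprotein and plasma protein genes 19 fell (20 adjusted over the list alone), in the brush border list 17 fell (19 adjusted over the list alone), among S phase genes 17 rose (19 adjusted over the list alone), and among goblet and mucus genes 5 fell and 1 rose (also adjusted over the list alone). The hypoxia and glycolysis list was called for shRNA#4, with 5 falls and 2 rises (6 and 2 adjusted over the list alone), and so was the NRF2 target and metallothionein list, with 4 rises (5 adjusted over the list alone). The limma camera adjusted p of these last lists was 0.0276 and 0.0461, with adjusted p = 0.435 with an estimated correlation for the first and adjusted p = 0.437 with an estimated correlation for the second. The hypoxia call ended without replicate 2 of scramble, and the NRF2 call without replicate 1 of scramble, without replicate 2 of shRNA#4 and with protein-coding genes alone. The lowest value over the 12 lists was a limma adjusted p = 0.0809 with an estimated correlation, again for the apolipoprotein and plasma protein list.

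The hairpins shared 2044 genes called in the same direction, 1159 higher and 885 lower. Independent lists of these sizes would share 281.9 and 148.16. Simulated unchanged groups with shared scramble arrays shared 0. Without changed genes almost none are called, so this 0 does not show how much the shared arrays add. Opposite calls were made for 100 genes, 31 higher with shRNA#2 and lower with shRNA#4 and 69 the reverse, where independent lists would give 410.2. A further 1076 genes were called for shRNA#2 only and 1740 for shRNA#4 only. The log2 changes against scramble correlated across genes at r = 0.728 (Spearman's rho 0.614), beside a mean of 0.4997 (rho 0.473) for simulated unchanged groups, and genes are not independent replicates. Their covariance was 0.0707 beside 0.00300 simulated, a difference of 0.0677. Under quantile normalization r between the hairpins was lower and nearer to the simulated mean, as given with the processing below. Without single arrays the same-direction count lay between 1263 and 1657 and the opposite count between 26 and 58. The 2 scramble arrays were not split between the comparisons, and part of the excess over independent lists may come from these shared arrays.

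**Figure D3:**
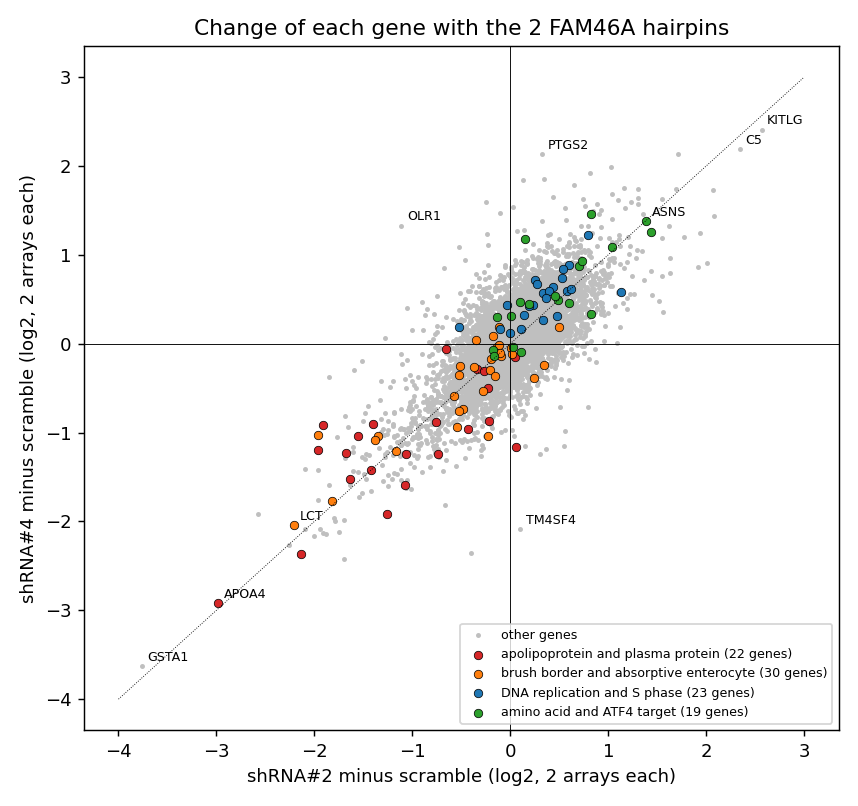
Log2 change with shRNA#2 (horizontal axis) and with shRNA#4 (vertical axis) against scramble, 1 point per gene, each change between groups of 2 arrays; colours mark 4 of the gene lists and the dotted line marks equal change. GSTA1 and APOA4 lie far down the line at about -3.76 and -2.98 for shRNA#2, KITLG and C5 far up at 2.56 and 2.35, while OLR1, TM4SF4 and PTGS2 lie away from it.

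The hairpins were then compared with each other. OLR1, a scavenger receptor for oxidised lipoprotein, was lower with shRNA#2 than with shRNA#4 by 2.44 on the log2 scale (-2.44 ± 0.18). It fell by 1.11 ± 0.18 with shRNA#2 and rose by 1.33 ± 0.18 with shRNA#4. TM4SF4 (2.19 ± 0.18) and HSD17B2, which inactivates oestradiol and testosterone (1.96 ± 0.21), were higher with shRNA#2, and against scramble both passed the test with shRNA#4 only, at -2.09 ± 0.18 and -2.36 ± 0.21. GALNT3, which starts mucin-type glycosylation, was higher with shRNA#2 by 1.70 ± 0.057, the collagenase MMP1 by 1.54 ± 0.14 and the metalloprotease ADAM9 by 1.54 ± 0.096. BAAT, which conjugates bile acids (-1.85 ± 0.18), PTGS2 (-1.81 ± 0.11), the TEAD cofactor VGLL1 (-1.71 ± 0.14) and the Wnt antagonist DKK1 (-1.62 ± 0.28) were lower with shRNA#2. The adjusted p-values of these 10 genes (limma, Benjamini-Hochberg) lay between 0.00111 for GALNT3 and 0.0158 for DKK1, and the call of DKK1 ended without replicate 1 of shRNA#2 or either array of shRNA#4.

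Between the hairpins 2272 of the 14884 genes differed, 988 higher and 1284 lower with shRNA#2, with 19 and 40 of them at least 2-fold. Camera called 5 lists. Mitosis and G2/M genes were higher with shRNA#2, 8 of 27 and 0 lower (11 and 2 adjusted over the list alone), among them ECT2 (0.54 ± 0.087), with a limma camera adjusted p of 6.02e-05, and adjusted p = 0.885 with an estimated correlation. S phase genes went the other way, 5 lower and 1 higher (6 and 1 adjusted over the list alone), with MCM10 at -0.43 ± 0.11 and MCM3 at -0.30 ± 0.072 but CCNE1 at 0.54 ± 0.046. Their limma camera adjusted p was 0.0092, and adjusted p = 0.885 with an estimated correlation. NRF2 target and metallothionein genes were lower with shRNA#2 in 5 of 13 (7 adjusted over the list alone), with MT1F at -1.48 ± 0.25 and TXNRD1 at -0.41 ± 0.062, at a limma camera adjusted p of 0.000539, and adjusted p = 0.747 with an estimated correlation. YAP targets were lower in 5 of 11 (8 lower and 1 higher adjusted over the list alone), with ANKRD1 at -1.14 ± 0.13 and CRIM1 at -0.52 ± 0.060, at a limma camera adjusted p of 0.00564, and adjusted p = 0.747 with an estimated correlation. Hypoxia and glycolysis genes were higher in 4 of 18 (6 higher and 1 lower adjusted over the list alone), with BNIP3 at 0.43 ± 0.073, at a limma camera adjusted p of 0.00621, and adjusted p = 0.828 with an estimated correlation. The apolipoprotein and plasma protein list and the brush border list did not pass camera between the hairpins, with medians of 0.082 and 0.0067. With fry the apolipoprotein list was called (adjusted p 0.0368), with 5 members higher and 4 lower with shRNA#2, and the brush border list was not (0.381). The number of called genes, FAM46A-shRNA#2 vs FAM46A-shRNA#4, was 761 without replicate 1 of shRNA#2, 1022 without its replicate 2, 1300 without replicate 1 of shRNA#4 and 1057 without its replicate 2. The S phase list was no longer called without replicate 2 of shRNA#2. With fry in place of camera the mitosis, S phase and hypoxia lists were not called. Fry called 8 lists, 2 of them shared with camera. Its further calls were the apolipoprotein, ER translocation, BMP and TGF-beta, NF-kappa-B, epithelial junction and mesenchymal lists.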

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

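The tests of a single unusual scramble array, of scaling for the brush border list, of a difference in the scramble cultures, of the spread between replicates, of which hairpin gave the larger change and of the opposite calls at the stricter thresholds were chosen only after the result was seen.

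The apolipoprotein and plasma protein list and the brush border list were lower with both hairpins. Scaling of the centred values of whole arrays did not account for this. Quantile normalization left the median change of the apolipoprotein list at -0.956, beside -1.151 before, and that of the brush border list at -0.286, beside -0.289. Scaling that depends on signal level could not be examined, because centring had removed the level of each probe set. A single scramble array did not account for the falls either. Over the 8 pairs of a hairpin array with a scramble array the median lay between -1.17 and -1.014 for the apolipoprotein list. For the brush border list it lay between -0.368 and -0.23. A difference between the scramble cultures and all hairpin cultures other than the target cannot be told apart from an effect of lower FAM46A, because there was 1 control hairpin, the target was not analysed here, and the apolipoprotein list differed between the hairpins by only 0.082. The fall may therefore be an effect of the target or of any other difference between the scramble cultures and the hairpin cultures.

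The mitosis and G2/M list differed between the hairpins by a test of the difference itself, with a median of 0.191, and the call was lost with an estimated correlation (limma adjusted p 0.885) and with fry (0.233). The gap between the nearest arrays of the hairpins was 0.152, which is 0.607 of the largest gap between replicates (0.25, in scramble). Both shRNA#2 arrays (medians 0.144 and 0.241) lay above both shRNA#4 arrays (-0.025 and -0.008), and the gap exceeded those between replicates of the hairpins themselves, of which the larger was 0.098. With 2 arrays per group the spread between replicates cannot be told apart from a difference between the hairpins in mitosis genes, which was not tested further.

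Between the hairpins 2272 genes differed, and 100 genes were called in opposite directions against scramble. The criterion set before the result was seen, at most 5% opposite calls, came out on the side of unequal knockdown of 1 target, with 3.106% of the calls of shRNA#2 (1.05% to 2.45% without single arrays, and 0.952% at an adjusted p under 0.01), but the shared scramble arrays favour the same sign in advance and the share decides nothing. If each gene follows the level of 1 target in 1 direction, unequal knockdown does not account for the differences as a whole, since of 479 genes called the same way by both hairpins and also called between them 160 changed more with shRNA#2 and 319 with shRNA#4, 33.4% on the smaller side (23.1% to 48.8% without single arrays, which left 103 to 384 genes, with 66 and 63 and so the other side larger without replicate 2 of shRNA#2). Nor does it account for the 8 genes changed by at least 0.5 in opposite directions, where replicate noise gave 0 to 2: OLR1, GALNT3, MMP1, CSGALNACT2, TNIK, CP, NDNF and GGCT, the last 5 named after their values were seen. Windows of 50 neighbouring genes showed no broad copy number difference between the infected populations. Of the genes called between the hairpins, 0% lay in windows whose median passed the permuted limit of 0.103. The windows held all 14883 placed genes, whatever their signal. How large a broad difference they could detect was not tested, so such differences are not excluded. Focal copy number changes, or changes in few cells, could also be missed by such windows and were not tested. Off-target effects and responses that turn with the level of the target were not tested.

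Other lists also differed between the hairpins by a test of the difference itself, with medians of -0.241 for YAP targets, -0.202 for S phase genes, 0.187 for hypoxia and glycolysis and -0.242 for NRF2 targets and metallothioneins. All 4 calls were lost with an estimated correlation (limma adjusted p 0.747, 0.885, 0.828 and 0.747), and those of S phase (0.302) and hypoxia (0.0817) also with fry. In data outside the named genes, 2846 of 32046 probe sets without a symbol passed the limma test for the mean of both hairpins, 1423 higher and 1423 lower. Against scramble, windows of 50 neighbours beyond the permuted limit numbered 9 for shRNA#2 (250 genes, 82 of them called), 2 for shRNA#4 (60 genes, 22 called) and 3 for the mean of both hairpins (150 genes, 61 called). No explanation was tested for these values.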

How the results depend on the processing

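The tests with protein-coding genes alone and of which hairpin gave the larger change were chosen only after the result was seen. No gene, list or correlation changed its direction past the threshold, while the hairpin with more of the larger changes switched without replicate 2 of shRNA#2. Of 2296 comparisons of named genes with an alternative, 2198 kept their side of the threshold, 16 gained a call and 82 lost it, and of 1856 for gene lists 1761 kept it, 34 gained and 61 lost. Of 178 counts and correlations 140 stayed within their limits and 38 moved. Values in groups of 4 follow the order of called genes, FAM46A-shRNA#2 vs scramble; called genes, FAM46A-shRNA#4 vs scramble; called genes, mean of both shRNAs vs scramble; and called genes, FAM46A-shRNA#2 vs FAM46A-shRNA#4. With an estimated correlation 0, 0, 0 and 0 lists were called, where the preset correlation called 11, 12, 13 and 5 and fry 14, 20, 15 and 8. The estimates were 0.5224 for the mitosis list and 0.3183 for the S phase list, above the preset 0.01. They were -0.0044 for the apolipoprotein list and 0.004 for the brush border list, below it. Correlation between genes therefore does not explain the lost calls of these last lists. Camera with an estimated correlation relies on 3 residual degrees of freedom, so its lack of calls decides little for any list or family. For the apolipoprotein list and the mean of both hairpins the unadjusted camera p (limma) was 3.36e-17 with the preset correlation and 0.00264 with the estimated one. A 2-fold minimum left 221, 279, 206 and 59 genes and an adjusted p under 0.01 left 1575, 2122, 2158 and 769, by construction. Over all probe sets 6300 were called for shRNA#4 and 6141 for the mean, where more were tested. With the 4 hairpin arrays as 1 group 1756 genes were called, since differences between the hairpins then count as spread. Under quantile normalization r between the hairpins was 0.561, where arrays with a wider spread are compressed. This is nearer to the mean of 0.4997 for unchanged groups, which was simulated without that normalization. Leaving out single arrays gave 1756 to 2982, 2677 to 3476, 2477 to 3358 and 761 to 2166 genes, 1263 to 1657 shared in the same direction, 26 to 58 in opposite directions, r of 0.700 to 0.752, and 11 to 12, 10 to 13, 12 to 14 and 4 to 6 lists. The lone array of a group is then assumed to vary like the other groups, and fewer arrays were fitted.

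The labels do not say that a replicate number marks a shared day. With a replicate block the called genes, FAM46A-shRNA#2 vs scramble, numbered 3598, the called genes, FAM46A-shRNA#4 vs scramble, 4227, the called genes, mean of both shRNAs vs scramble, 4160, and the called genes, FAM46A-shRNA#2 vs FAM46A-shRNA#4, 2637. The genes called for both shRNAs in the same direction numbered 2305, and the lists 11, 13, 13 and 5. Deviations of same-numbered arrays correlated at 0.179 (scramble and shRNA#2), 0.119 (scramble and shRNA#4) and 0.199 (both hairpins). Filters on dim probe sets, the log transform with an offset and the level of FAM46A were not run, and signal over background was not analysed here.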

Other observations

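All tests in this part were chosen only after the result was seen. Genes were grouped by the letters that open their symbols, and the 168 families with at least 10 measured members were tested with camera (limma) for the mean of both hairpins against scramble and between the hairpins.

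Nucleoporin genes (NUP) had 14 of 24 members higher and 0 lower, with a median of 0.23 and an adjusted p of 0.000111 (limma), and adjusted p = 0.668 with an estimated correlation. NUP205 rose by 0.83 ± 0.052 and NUP210 by 0.68 ± 0.052. Centrosomal genes (CEP) had 20 of 38 higher and 1 lower, with a median of 0.29. The RAD genes, largely of DNA repair, had 9 of 17 higher and 0 lower, with RAD54B at 0.83 ± 0.088 and RAD51C at 0.63 ± 0.048. Heat shock genes of the HSPA family had 8 of 12 higher and 0 lower, with a median of 0.37, exosome subunits (EXOSC) 7 of 10 higher and 0 lower, and HOXB genes 5 of 10 higher and 0 lower. Zinc finger genes (ZNF) had 127 of 476 higher and 16 lower, with a median of 0.077. Aquaporins (AQP) went the other way, with 0 of 14 higher and 3 lower, AQP3 at -1.40 ± 0.063, AQP10 at -1.27 ± 0.19 and AQP11 at -0.53 ± 0.086. The families above were picked from those called. Also called were MRPL (17 of 50 higher, 2 lower), MRPS (9 of 26 higher, 2 lower) and MCM (6 of 10 higher, 0 lower). The same held for DDX (12 of 36 higher, 0 lower), DHX (8 of 16 higher, 1 lower) and TIMM (6 of 13 higher, 0 lower). The camera adjusted p-values (limma) of the called families lay between 0.000111 and 0.0408. Between the hairpins ZNF genes were lower with shRNA#2, 73 lower and 12 higher with a median of -0.067, and HOXB genes higher, 3 of 10 and 0 lower with a median of 0.19, each at a camera adjusted p of 0.0369 (limma), and adjusted p = 0.963 with an estimated correlation. With an estimated correlation none of the 168 families passed in either comparison, and 0.668 was the lowest limma adjusted p.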
